A study of Mus musculus with 12 samples.

How the data were processed

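RNA from the hippocampus of C57BL/6 mice at postnatal day 25 was sequenced in 12 libraries. They form 4 groups of 3: wild-type males, males heterozygous for a frameshift mutation of Chd8, wild-type females, and heterozygous females. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. Libraries were made with the TruSeq RNA Sample Prep Kit v2, per the labels' protocols, a kit that does not keep the strand of a transcript. Reads of overlapping genes on opposite strands could therefore not be told apart.

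The submitters' processing notes name Trimmomatic 0.35, TopHat2 2.1.0, HTSeq, DESeq2 and the mouse genome build GRCm38, without giving their roles or order. The annotation release is not given in the sources used here. The deposited values are a signal per Ensembl gene: read counts divided by 1 size factor per library. This was read from the values themselves, since every value of a library was a whole multiple of the same step, from 0.807 to 1.13 normalized counts per read. All values came out whole, 100% in each library, within a tolerance of 1e-06 reads. The steps equalled the inverse of the median-ratio size factors recomputed from the recovered reads. The table held no columns of other samples (0) and 46078 gene IDs, of which 45143 had a symbol and a position in GENCODE M21, an annotation of GRCm38, and 935 did not. Coordinates are 1-based positions on GRCm38 from that annotation.

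Recovered reads per library, as the depth behind each value, were 26912998, 28149825 and 33327314 in wild-type males, 30016094, 30254747 and 32284243 in wild-type females, 24173687, 23721482 and 24654408 in mutant males, and 23908719, 24580863 and 23803605 in mutant females. Every mutant library lay below every wild-type library, so depth and genotype were confounded. No sequencing batch or date is in the labels used here. Duplicate libraries were looked for with a chi-square test of recovered reads within each group. The statistic per degree of freedom was 3.38 to 30.0, so no pair lay within sampling noise.

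The design assumed raw counts and named a fallback for values already divided by size factors, and the fallback was used. Values were transformed as log2(value + 1), genes with a mean of at least 10 were kept (17496 of 46078 IDs, 17416 of them with a symbol, with 28582 not tested), and limma 3.58.1 in R 4.3.3 was fitted with its trend option and 1 mean per group over all 12 libraries. A fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. Contrasts were mutant minus wild type in males, in females and averaged over both sexes, the difference between the male and female genotype effects, and male minus female within each genotype. P-values were adjusted with the Benjamini-Hochberg method over all tested genes at a threshold of 0.05, and every adjusted p of a gene is from limma unless another tool is named.

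Chd8 was also tested by exact two-sided permutation of its log2 values, where the design had named the normalized values without a scale: 3 libraries against 3 allow no p below 0.1, and permuting genotype within each sex gives 400 arrangements and no p below 0.005. List scores were tested in the same way. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 38 lists. The 19 cell type lists covered pyramidal, CA1, CA3, dentate, inhibitory and immature neurons, proliferating cells, astrocytes, oligodendrocytes, their precursors, microglia, endothelial cells, pericytes, choroid plexus, ependyma, fibroblasts, red blood cells, thalamus and neocortex. The 19 functional lists covered activity-regulated genes, CHD proteins, Wnt and p53 targets, autism risk genes, synaptic vesicles, the postsynaptic scaffold, glutamate and GABA receptors, neuropeptides, extracellular matrix, ribosomal proteins, nuclear-encoded and mitochondrially encoded respiratory genes, splicing, interferon, glucocorticoid and heat shock responses, and cholesterol synthesis. The list called pericytes also held smooth muscle genes. A further 3 lists of Y-linked, X-inactivation and escape genes served as a check of sex labels. A list score is the mean of log2(value + 1) over the list's genes in a library. In the main fit every camera adjusted p of a called list is given with its counterpart from a correlation estimated from the data. With that estimate 0 lists passed in any genotype contrast. The test fry, which asks whether a list's own genes move on balance one way, also called 0. Under the alternatives, adjusted p-values of lists are from camera at the preset correlation alone unless another test is named.

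Gene lists, contrasts, the test with its fallback, the rule for named genes and the processing alternatives were fixed before the data were examined. The rule named, per genotype contrast, up to 10 higher and 10 lower genes with the smallest p past the threshold and, where fewer than 10 passed, the 5 higher and 5 lower genes with the smallest unadjusted p, given as not past it. It named the 5 higher and 5 lower genes with the smallest p in each sex contrast, up to 4 members with the smallest p of each list described, and always Chd8 and the sex check genes. IDs without a symbol were skipped. Some members of the lists are not reported here.

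Alternatives were TMM factors (edgeR 4.0.16) on top of the deposited values, upper-quartile factors, library totals, no filter, a minimum mean of 50, pseudocounts of 0.5 and 5, limma-voom, edgeR's quasi-likelihood test and DESeq2 1.42.0 (Wald test, default settings, 0.05) on the recovered reads of the same genes, 1 surrogate variable (sva 3.50.0), a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were the choroid plexus score as a covariate, leaving out the 3 libraries lowest in choroid plexus markers, and thinning reads to the smallest library. The pipeline was tested on simulated counts with known changes in males among 17488 genes. It recovered 16% of genes changed 1.25-fold, 52% at 1.5-fold, 76% at 2-fold and 92% at 3-fold, each out of 50, with 6 false calls among 17269 unchanged genes. The simulated counts were drawn independently for each gene. They lacked the choroid plexus differences that the real libraries share across genes, so these rates need not hold for the real data. IDs were matched after removing version suffixes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.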

Results

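Hippocampal RNA of mice at postnatal day 25 was compared between wild-type animals and carriers of a heterozygous frameshift mutation of Chd8, which encodes a chromatin remodelling enzyme, in 3 libraries of each genotype and sex. Log2 fold changes of genes are given ± standard error, and levels ± SD. Adjusted p-values of genes, and counts of genes past 0.05, are from limma unless another test is named. The groups differed in ways other than genotype. Recovered reads numbered 23721482 to 24654408 per mutant library and 26912998 to 33327314 per wild-type library. Markers of choroid plexus, the secretory tissue that lies beside the hippocampus in the ventricle, differed more than any other marker list between the libraries of mutant males and of wild-type females. Their mean log2 level was 5.05 in wild-type female 1, 5.33 in mutant male 2 and 5.65 in mutant male 3, and 9.004 to 10.75 in the other 9 libraries. Ttr, which encodes the transport protein transthyretin, had normalized counts of 167 to 274 in these 3 libraries and of 43047 to 156059 in the other 9. Group means of the choroid plexus score (± SD, n = 3) were 10.55 ± 0.17 in wild-type males, 7.20 ± 2.96 in mutant males, 8.24 ± 2.88 in wild-type females and 9.92 ± 0.55 in mutant females.

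**Figure D1:**
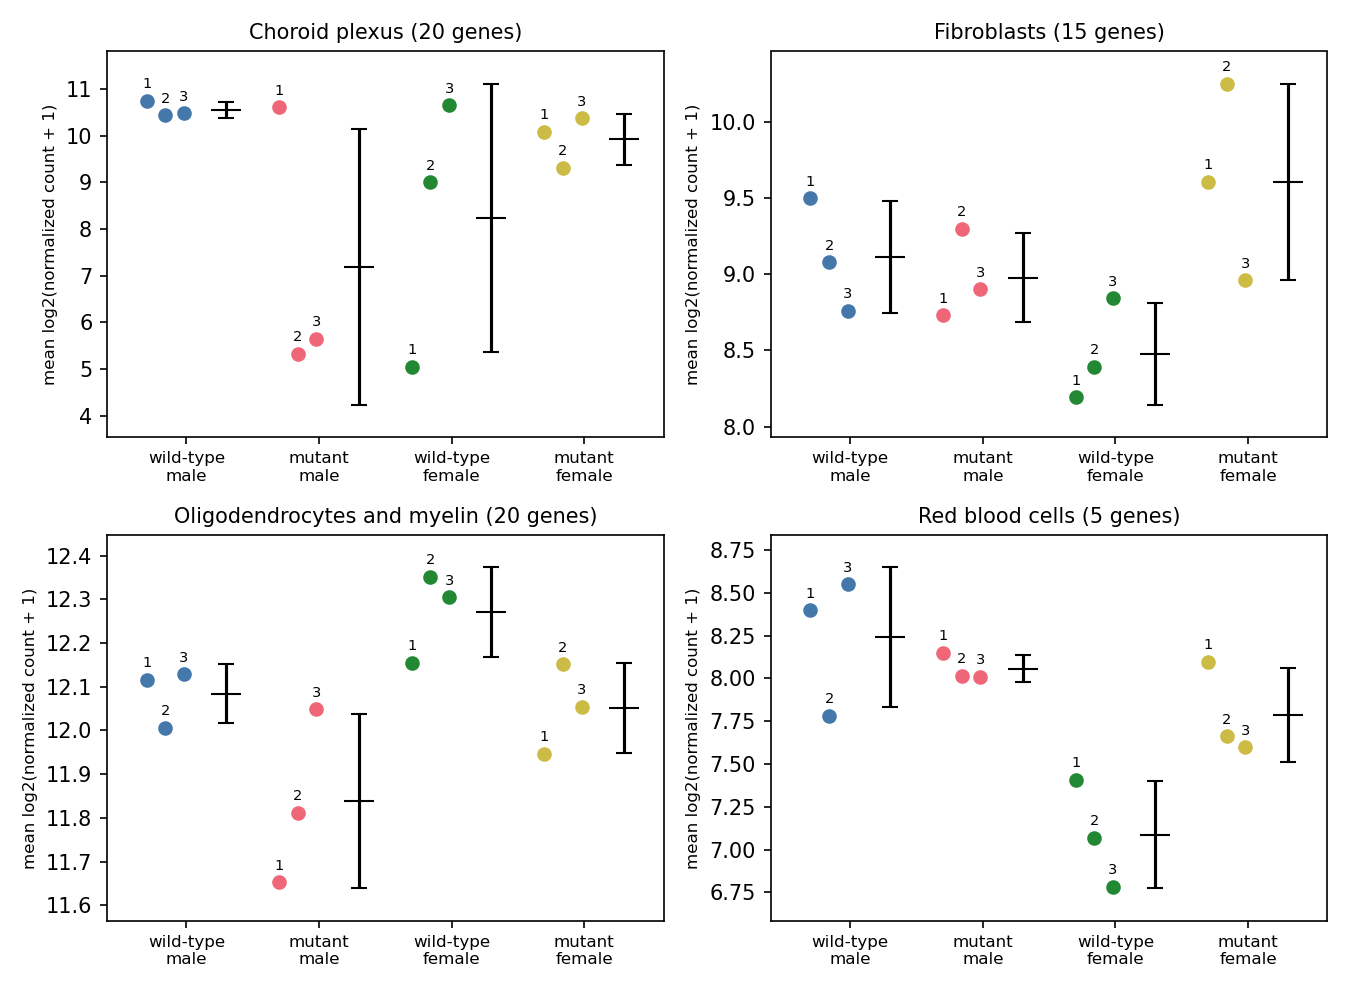
Mean log2(normalized count + 1) of the markers of choroid plexus, fibroblasts, myelin and red blood cells in each library, numbered by replicate, with the mean and SD of each group of 3. The choroid plexus panel holds 3 low libraries, at 5.05, 5.33 and 5.65.

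Chd8 transcripts themselves were lower in mutants of both sexes, which answered whether the mutated gene was expressed at a different level. Normalized counts (± SD, n = 3) were 2866 ± 122 in wild-type males and 2438 ± 64 in mutant males, and 2870 ± 24.1 in wild-type and 2472 ± 43.6 in mutant females. Every mutant library (2383 to 2513) lay below every wild-type library (2751 to 2994). Averaged over both sexes, Chd8 fell by 14.4% (95% interval 10.97 to 17.70%; log2 fold change -0.22, standard error 0.03; limma adjusted p = 0.0289), with an exact permutation p of 0.005, the smallest that 400 arrangements within the sexes allow. In males alone it was 14.9% lower (10.1 to 19.5%; log2 -0.23, adjusted p = 0.320) and in females 13.9% lower (8.96 to 18.5%; log2 -0.22, adjusted p = 0.584), neither past the threshold among 17496 genes, with an exact permutation p of 0.1 in each sex, the smallest possible for 3 against 3. The difference between the sexes was -0.02 on the log2 scale (exact permutation p = 0.880). Of 14 other tested genes within 500 kb of Chd8, log2 differences ran from -0.11 to 0.15 and 1 had an unadjusted p under 0.05, Arhgef40 (0.15, adjusted p = 0.341). The averaged Chd8 call rested on nearly every library. Its log2 value stayed between -0.24 and -0.21 without any 1 of them, but its adjusted p rose above 0.05 without wild-type male 2 (0.0851) or 3 (0.162), wild-type female 1 (0.0807), 2 (0.111) or 3 (0.107), mutant male 1 (0.122) or 2 (0.140), and mutant female 1 (0.156), 2 (0.0788) or 3 (0.109). The call was also lost with upper-quartile factors (adjusted p = 0.0672), without a filter on low genes (0.0538) and with the replicate number as a block (0.131).

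**Figure D2:**
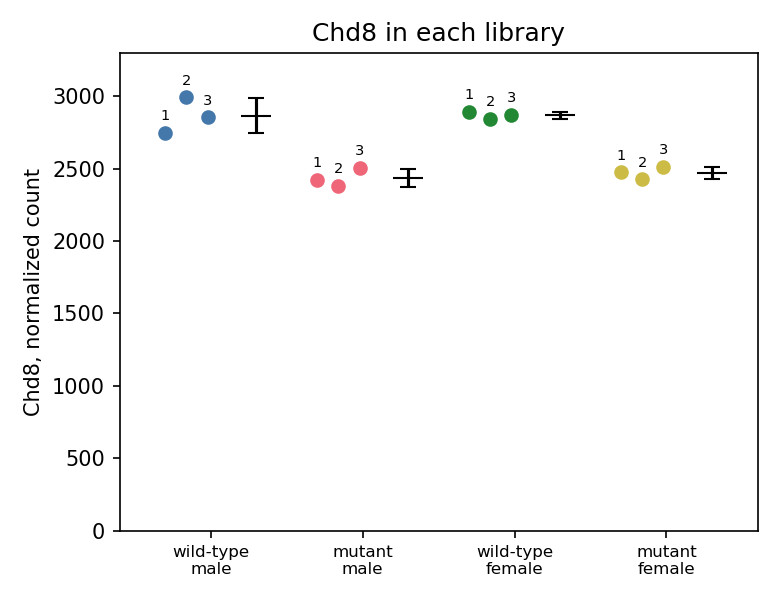
Normalized counts of Chd8 in each library, numbered by replicate, with the mean and SD of each group of 3. Group means were 2866 and 2870 in wild-type males and females and 2438 and 2472 in mutant males and females.

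Averaged over both sexes, the comparison of mutants with wild type asked which genes and cell types differed with genotype in both sexes together. Genes of oligodendrocytes and the myelin sheath were lower in mutants of both sexes, with smaller differences in most other groups. Beyond Chd8, 0 genes passed limma's threshold, while 1552 had an unadjusted p under 0.05 against 875 expected by chance. The number past 0.05 was 1 with edgeR, 1 with limma-voom and 75 (18 higher, 57 lower) with DESeq2. It was 0 with upper-quartile factors, without a filter and with a replicate block. Leaving out single libraries gave 0 to 8 genes: Chd8 alone without wild-type male 1, 8 lower genes including Chd8 without mutant male 3, Hjurp alone (0.28, adjusted p = 0.00994) without mutant female 2, and 0 without any of the other 9. Without the 3 libraries lowest in choroid plexus markers the number was 82 (7 higher, 75 lower), a comparison in which mutant males had 1 library.

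All 20 measured genes of the myelin list were lower in mutants (mean log2 -0.23, camera adjusted p = 6.56e-20, adjusted p = 0.456 with an estimated correlation). Of these, 19 had an adjusted p under 0.05 when adjusted over the list alone and 0 when adjusted over all genes by limma, while DESeq2 called 8 of the list over all genes. Mobp, a structural protein of compact myelin, stood at -0.31 ± 0.06 (19.4% lower, adjusted p = 0.285, and 0.00114 with DESeq2). Enpp6, a marker of oligodendrocytes that have just begun to form myelin, stood at -0.33 ± 0.08 and Tspan2 at -0.23 ± 0.06. Myelin scores (± SD, n = 3) were 12.08 ± 0.07 and 11.84 ± 0.20 in wild-type and mutant males, and 12.27 ± 0.10 and 12.05 ± 0.10 in wild-type and mutant females. The mean score difference had an exact permutation p of 0.015 within the sexes, which was 0.285 after adjustment over 38 lists. The other exact permutation p-values under 0.05 were 0.005 for GABA receptors, 0.0400 for pericytes and 0.0450 for splicing genes, with 0.190, 0.427 and 0.427 after adjustment. The mutant libraries were also the less deeply sequenced.

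Oligodendrocyte precursor genes were lower by less (mean log2 -0.07, camera adjusted p = 0.0121, adjusted p = 0.471 with an estimated correlation), with 9 of 12 negative and 1 past 0.05 when adjusted over the list alone against 0 over all genes. DESeq2 called 1 of them over all genes, Olig1 (0.0114). Olig1 and Olig2, transcription factors of the lineage, stood at -0.18 ± 0.04 and -0.15 ± 0.06, and Gpr17, a receptor of cells about to differentiate, at -0.20 ± 0.07. For precursors the call was lost without mutant male 1 (-0.04, adjusted p = 0.119).

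Markers of pyramidal neurons were higher in 9 of 10 genes (mean log2 0.08, camera adjusted p = 0.00198, adjusted p = 0.456 with an estimated correlation), with Neurod2 at 0.11 ± 0.04 and Slc17a7 at 0.07 ± 0.02. Their mean was 0.16 in males and 0.0087 in females. Without wild-type female 3 the averaged mean was 0.04, adjusted p = 0.0454. Activity-regulated genes were higher in 27 of 37 (mean log2 0.07, camera adjusted p = 8.15e-04, adjusted p = 0.456 with an estimated correlation), with Nptx2 at 0.27 ± 0.08, and the mean was 0.04, adjusted p = 0.0151 without wild-type female 3. Inhibitory neuron markers were higher in 13 of 14 (mean log2 0.05, camera adjusted p = 0.0160, adjusted p = 0.459 with an estimated correlation), including Gad2, a GABA-synthesizing enzyme, at 0.10 ± 0.04. For inhibitory neurons the call was lost without wild-type male 1 (0.04, adjusted p = 0.109), wild-type female 3 (0.03, adjusted p = 0.142), mutant male 3 (0.03, adjusted p = 0.0916) and mutant female 3 (0.04, adjusted p = 0.0595). Immature neuron genes were higher in 10 of 12 (mean log2 0.08, camera adjusted p = 0.0160, adjusted p = 0.456 with an estimated correlation), with 3 past 0.05 when adjusted over the list alone and 0 over all genes. Draxin, an axon guidance protein, stood at 0.30 ± 0.08. For immature neurons the call was lost without wild-type female 1 (0.06, adjusted p = 0.0559), mutant male 1 (0.08, adjusted p = 0.0615) and mutant female 2 (0.04, adjusted p = 0.0619), and kept but with a mean of 0.12 without mutant female 3. For neuropeptides 17 of 22 were higher (mean log2 0.14, camera adjusted p = 0.0121, adjusted p = 0.456 with an estimated correlation), with Scg2 at 0.13 ± 0.03 and Cck at 0.15 ± 0.04, and 2 past 0.05 when adjusted over the list alone against 0 over all genes (DESeq2 called Scg2 (0.0336)). For neuropeptides the call was lost without wild-type female 3 (0.11, adjusted p = 0.0687) and mutant male 1 (0.05, adjusted p = 0.0615). With a minimum mean of 50 the mean was 0.06, adjusted p = 0.0392. Without the 3 libraries lowest in choroid plexus markers, which left 1 mutant male, it was 0.28.

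Receptor and synapse lists moved by little, in samples whose choroid plexus genes had an averaged mean of -0.84. GABA receptor genes were higher in 14 of 15 (mean log2 0.06, camera adjusted p = 0.0291, adjusted p = 0.456 with an estimated correlation). With a minimum mean of 50 their mean was 0.04, adjusted p = 0.0540. For GABA receptors the call was lost without wild-type male 1 (0.06, adjusted p = 0.103), wild-type female 3 (0.05, adjusted p = 0.236), mutant male 2 (0.07, adjusted p = 0.0649), mutant female 1 (0.06, adjusted p = 0.0665) and mutant female 3 (0.06, adjusted p = 0.0685). Synaptic vesicle genes had a mean log2 fold change of 0.02 (camera adjusted p = 0.0160, adjusted p = 0.615 with an estimated correlation), with Syn1 at 0.07 ± 0.03. For vesicle genes the call was lost without wild-type male 1 (0.01, adjusted p = 0.0727), wild-type female 2 (0.01, adjusted p = 0.0541), wild-type female 3 (-0.0031, adjusted p = 0.223), mutant male 2 (0.01, adjusted p = 0.0590), mutant male 3 (0.01, adjusted p = 0.0505) and mutant female 3 (0.01, adjusted p = 0.0685), and kept but with a mean of 0.02 without wild-type male 2 and 0.04 without wild-type female 1. Genes of the postsynaptic scaffold had a mean log2 fold change of 0.02 (camera adjusted p = 0.0457, adjusted p = 0.731 with an estimated correlation), with Nlgn3, an adhesion protein of the synapse, at -0.10 ± 0.03. For scaffold genes the call was lost without wild-type male 1 (0.01, adjusted p = 0.206), wild-type female 3 (0.0023, adjusted p = 0.662), mutant male 2 (0.01, adjusted p = 0.358), mutant male 3 (0.02, adjusted p = 0.0725), mutant female 1 (0.01, adjusted p = 0.185) and mutant female 3 (0.02, adjusted p = 0.111), and kept but with a mean of 0.03 without mutant male 1. Astrocyte markers had a mean log2 fold change of 0.05 (camera adjusted p = 0.0232, adjusted p = 0.615 with an estimated correlation), with the gap junction gene Gjb6 at 0.30 ± 0.12. For astrocytes the call was lost without wild-type male 1 (0.04, adjusted p = 0.115), wild-type female 3 (0.03, adjusted p = 0.305) and mutant male 3 (0.03, adjusted p = 0.247). With the choroid plexus score as a covariate the averaged calls of GABA receptors (0.07, adjusted p = 0.0823), vesicle genes (-0.0013, adjusted p = 0.227), and scaffold genes (0.01, adjusted p = 0.370) were lost. So were those of astrocytes (0.03, adjusted p = 0.212) and inhibitory neurons (0.04, adjusted p = 0.0704).

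Vascular and connective tissue markers were higher in the average over both sexes. Of these lists only pericytes and smooth muscle, as 1 list, were called in males. Mean log2 fold changes in males and females were -0.14 and 1.13 for fibroblasts and -0.05 and 0.48 for extracellular matrix. They were 0.02 and 0.17 for endothelial cells, -0.18 and 0.70 for red blood cells and 0.41 and 0.42 for pericytes and smooth muscle. Endothelial markers were higher in 13 of 14 (mean log2 0.09, camera adjusted p = 0.00167, adjusted p = 0.459 with an estimated correlation), with Tek, a receptor of blood vessel lining, at 0.19 ± 0.06, and the mean was 0.06, adjusted p = 0.0253 without mutant female 2. Pericyte and smooth muscle markers were higher in 11 of 12 (mean log2 0.41, camera adjusted p = 8.51e-05, adjusted p = 0.456 with an estimated correlation), with Vtn at 0.48 ± 0.16 and Cnn1, a protein of contractile cells, at 1.59 ± 0.52. Without mutant female 2 their mean was 0.27, adjusted p = 0.00156. Fibroblast genes were higher in 14 of 15 (mean log2 0.50, camera adjusted p = 2.47e-05, adjusted p = 0.456 with an estimated correlation), with Col3a1 at 0.95 ± 0.34. Extracellular matrix genes had a mean log2 fold change of 0.21 (camera adjusted p = 2.18e-06, adjusted p = 0.459 with an estimated correlation), with the basement membrane collagen Col4a1 at 0.12 ± 0.04, and a mean of 0.12, adjusted p = 0.00134 without mutant female 2. Red blood cell genes had a mean log2 fold change of 0.26 (camera adjusted p = 0.0120, adjusted p = 0.533 with an estimated correlation). For red blood cells the call was lost without wild-type male 2 (0.14, adjusted p = 0.0525), wild-type female 3 (0.18, adjusted p = 0.0687) and mutant female 1 (0.18, adjusted p = 0.0656). Choroid plexus markers had a mean log2 fold change of -0.84 (camera adjusted p = 0.0160, adjusted p = 0.815 with an estimated correlation), with Enpp2 at -0.74 ± 0.68. Their score was lower in mutant males (7.20 against 10.55) and higher in mutant females (9.92 against 8.24). For choroid plexus the call was lost without wild-type female 2 (-0.64, adjusted p = 0.0801), wild-type female 3 (-0.23, adjusted p = 0.662), mutant male 2 (-0.37, adjusted p = 0.358), mutant male 3 (-0.45, adjusted p = 0.302) and mutant female 2 (-0.68, adjusted p = 0.0784), and kept but with a mean of -1.63 without wild-type female 1 and -1.69 without mutant male 1. Markers of ependyma, the ciliated lining of the ventricle, were lower in all 11 genes (mean log2 -0.33, from -0.73 in males and 0.06 in females, camera adjusted p = 0.00167, adjusted p = 0.549 with an estimated correlation), with Hydin at -0.36 ± 0.19. The call was kept at -0.51 without wild-type female 1, -0.21 without wild-type female 3 and -0.18 without mutant male 2.

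Genes for splicing had a mean log2 fold change of -0.02 (camera adjusted p = 0.00786, adjusted p = 0.521 with an estimated correlation), with the RNA-binding Hnrnpm at -0.08 ± 0.02. For splicing genes the call was lost without mutant male 3 (-0.02, adjusted p = 0.0505). Cholesterol synthesis genes had a mean log2 fold change of -0.03 (camera adjusted p = 0.0121, adjusted p = 0.611 with an estimated correlation), with Lss, an enzyme of the pathway, at -0.11 ± 0.03. For cholesterol synthesis the call was lost without wild-type female 2 (-0.02, adjusted p = 0.0801), mutant male 1 (-0.03, adjusted p = 0.0614), mutant male 2 (-0.02, adjusted p = 0.0649) and mutant female 1 (-0.02, adjusted p = 0.0665). Of the 38 lists, 20 were called (14 higher, 6 lower). With an estimated correlation 0 were, and fry called 0 (smallest adjusted p = 0.346). Among the 18 lists not called, the cell types were, with mean log2 fold change and camera adjusted p, CA1 pyramidal neurons (0.12, 0.520), CA3 pyramidal neurons (0.02, 0.708), dentate granule cells (0.01, 0.471), proliferating cells (0.01, 0.650), microglia (0.01, 0.699), thalamus and habenula (-0.02, 0.699) and neighbouring neocortex (0.02, 0.993). The functional lists not called were CHD family and partners (-0.01, 0.699), Wnt pathway targets (0.04, 0.221), p53 targets (-0.01, 0.524), autism risk genes (0.01, 0.343) and glutamate receptors (0.02, 0.0649). They also held cytosolic ribosomal proteins (-0.01, 0.520), nuclear-encoded respiratory genes (0.01, 0.0541), mitochondrially encoded proteins (0.03, 0.520), interferon response (0.05, 0.326), glucocorticoid response (-0.02, 0.520) and heat shock and protein folding (0.0023, 0.699).

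**Figure D3:**
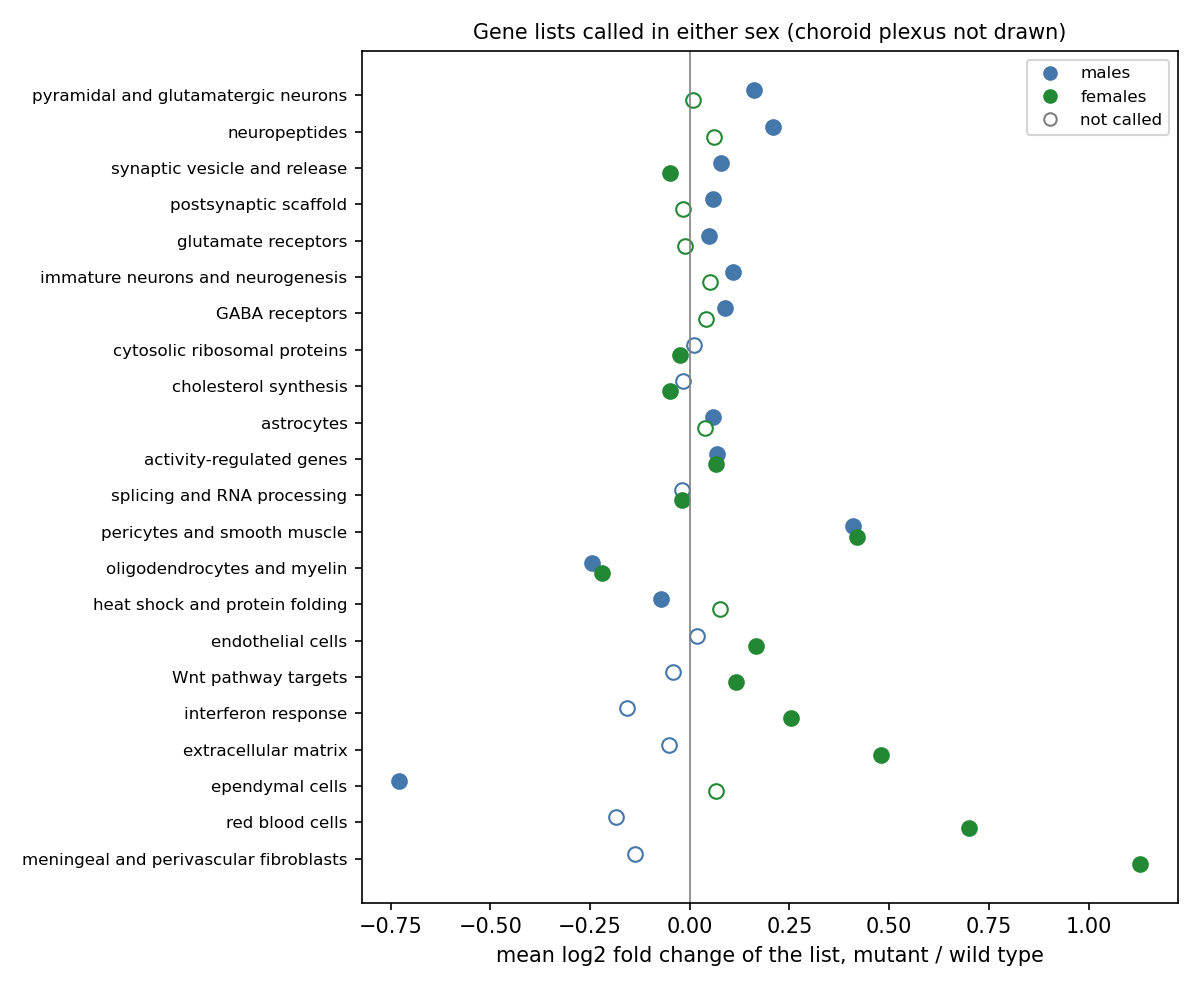
Mean log2 fold change, mutant against wild type, of the gene lists called in males or in females, with filled points where called, open points where not, and the choroid plexus list not drawn. Oligodendrocyte and myelin genes lay at -0.25 in males and -0.22 in females.

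No other single gene passed the threshold of limma in the averaged comparison, and the following are values only. The higher genes with the smallest p were Basp1 (0.19 ± 0.04, 14.4% higher), Crlf2 (0.34 ± 0.07, 26.6% higher), Pcdh8 (0.17 ± 0.03, 12.5% higher), Eid2 (0.16 ± 0.03, 11.9% higher) and Gdf10 (0.27 ± 0.06, 20.5% higher), all with an adjusted p of 0.285. Basp1 encodes a membrane protein of growing axons and Pcdh8 a protocadherin. The lower genes were 2610008E11Rik (-0.20 ± 0.03, 12.7% lower), March8 (-0.27 ± 0.04, 16.9% lower), Stxbp2 (-0.23 ± 0.04, 15% lower) and Gm37111 (-0.38 ± 0.07, 23.1% lower), with adjusted p of 0.191, 0.199, 0.285 and 0.285. Of these genes DESeq2 called March8 (4.01e-05), Basp1 (0.00169), Stxbp2 (0.00299), 2610008E11Rik (0.00299), Gm37111 (0.00371), Crlf2 (0.0151), Pcdh8 (0.0285) and Gdf10 (0.0336), with its adjusted p. March8 encodes a ubiquitin ligase, and Gm37111 lies just downstream of Mobp on the same strand.

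In males, mutants had lower levels of myelin genes and higher levels of genes of pyramidal neurons, immature neurons and synapses. Choroid plexus and ependymal genes were lower too. Leaving out the 3 libraries lowest in choroid plexus markers left 1 mutant male. The means were then 0.05 for choroid plexus and -0.20 for ependyma. They were 0.0084 for the postsynaptic scaffold, -0.03 for glutamate receptors and 0.02 for activity-regulated genes, but 0.16 for GABA receptors and 0.09 for pyramidal neurons. No gene passed limma's threshold (smallest adjusted p = 0.320, Chd8), and 1807 had an unadjusted p under 0.05 against 875 expected. Past 0.05 were 0 genes with edgeR, 0 with limma-voom and 35 (23 higher, 12 lower) with DESeq2, and 12 without the 3 libraries lowest in choroid plexus markers. That comparison had 1 mutant male library, and its spread came from the other groups. Without mutant male 2 there was 1, Wdfy1 (0.50, adjusted p = 0.0250). Of 38 lists, 14 were called (10 higher, 4 lower), with 0 called by an estimated correlation and 0 by fry (smallest adjusted p = 0.217). With 3 libraries against 3 the smallest exact p of a list score is 0.1. The labels do not state that the libraries of a group came from separate animals, so p-values here may measure only the spread between these samples.

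Every one of the 20 myelin genes was lower in mutant males (mean log2 -0.25, camera adjusted p = 7.09e-12, adjusted p = 0.437 with an estimated correlation), from -0.37 to -0.14. Mobp (-0.31 ± 0.09, 19.2% lower), Enpp6 (-0.37 ± 0.11) and Cldn11, a junction protein of myelin (-0.25 ± 0.08), were among the genes with the smallest p. Adjusted over the list alone, 7 passed, and over all genes 0 did, with 1 called by DESeq2, Mobp (0.0495). The library with the lowest myelin score was mutant male 1 (11.65). Without it the mean was -0.15, adjusted p = 4.03e-05. Without the 3 libraries lowest in choroid plexus markers, which left only mutant male 1, the mean was -0.43. Of the 3 mutant males 2 lay below all wild-type males.

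Pyramidal neuron markers were higher in all 10 genes (mean log2 0.16, camera adjusted p = 1.62e-05, adjusted p = 0.437 with an estimated correlation). Slc17a7 went from 33214 to 36792 normalized counts. The values of Slc17a7, Neurod2 and Nrgn, a calcium signalling protein of dendrites, were 0.15 ± 0.03, 0.21 ± 0.05 and 0.21 ± 0.06, and 3 of the list passed when adjusted over the list alone against 0 over all genes by limma. DESeq2 called Slc17a7 (0.00191), Neurod2 (0.0495) and Nrgn (0.0495) over all genes. Immature neuron genes were higher in 9 of 12 (mean log2 0.11, camera adjusted p = 0.00524, adjusted p = 0.437 with an estimated correlation), with Draxin at 0.47 ± 0.11 and Neurod1, a transcription factor of newborn granule neurons, at 0.27 ± 0.08. Adjusted over the list alone 3 passed, and 0 over all genes. For immature neurons the call was lost without mutant male 1 (0.11, adjusted p = 0.0533), and kept but with a mean of 0.17 without wild-type male 1 and 0.06 without wild-type male 2. Activity-regulated genes were higher in 26 of 37 (mean log2 0.07, camera adjusted p = 0.00696, adjusted p = 0.437 with an estimated correlation), with Nr4a3 at 0.15 ± 0.04, Nptx2 at 0.40 ± 0.12 and the growth factor Bdnf at 0.24 ± 0.08. Neuropeptide genes were higher in 16 of 22 (mean log2 0.21, camera adjusted p = 0.00710, adjusted p = 0.437 with an estimated correlation), with Scg2 at 0.22 ± 0.04 and Cck at 0.26 ± 0.06, 2 past 0.05 when adjusted over the list alone and 0 over all genes. DESeq2 called Scg2 (0.00403) and Cck (0.00847) over all genes. For neuropeptides the call was lost without mutant male 1 (0.06, adjusted p = 0.110). It was also lost with a minimum mean of 50 (0.08, adjusted p = 0.0538). That minimum leaves out low genes such as Trh, with 0.807 to 11.9 normalized counts in wild-type and 7.61 to 69.6 in mutant males. Neuron lists not called in males were inhibitory neurons (0.05, camera adjusted p = 0.151), dentate granule cells (0.02, 0.379), CA1 (-0.03, 0.894) and CA3 neurons (0.00097, 0.659). Choroid plexus scores were 10.55 ± 0.17 in wild-type and 7.20 ± 2.96 in mutant males.

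Synaptic genes followed the same direction. Vesicle genes were higher in 29 of 32 (mean log2 0.08, camera adjusted p = 1.82e-07, adjusted p = 0.437 with an estimated correlation), with Syn1, which tethers vesicles, at 0.14 ± 0.04 and Syp at 0.12 ± 0.04, and 1 past 0.05 when adjusted over the list alone against 0 over all genes. GABA receptor genes were higher in 14 of 15 (mean log2 0.09, camera adjusted p = 5.10e-04, adjusted p = 0.413 with an estimated correlation), with Gabra4 at 0.12 ± 0.04 and Gabrd at 0.18 ± 0.08, and a mean of 0.05, adjusted p = 0.00184 without mutant male 1. Postsynaptic scaffold genes were higher in 27 of 30 (mean log2 0.06, camera adjusted p = 2.97e-04, adjusted p = 0.520 with an estimated correlation), with Lrrtm1 at 0.15 ± 0.04. For scaffold genes the call was kept but with a mean of 0.03 without mutant male 2. Glutamate receptor genes had a mean log2 fold change of 0.05 (camera adjusted p = 0.00696, adjusted p = 0.625 with an estimated correlation), with Grik5 at 0.13 ± 0.04. For glutamate receptors the call was lost without mutant male 3 (0.02, adjusted p = 0.0694), and kept but with a mean of 0.09 without mutant male 1. With the choroid plexus score as a covariate the calls of vesicle (0.01, adjusted p = 0.0690), scaffold (0.01, adjusted p = 0.612), glutamate receptor (-0.05, adjusted p = 0.612) and activity-regulated genes (-0.0036, adjusted p = 0.540) were lost. So were those of pericytes (0.09, adjusted p = 0.704) and astrocytes (-0.03, adjusted p = 0.540). The pyramidal list was still called, with a mean of 0.07, adjusted p = 9.02e-04.

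Choroid plexus genes were lower in all 20 (mean log2 -3.36, camera adjusted p = 7.09e-12, adjusted p = 0.465 with an estimated correlation), 16 of them past 0.05 when adjusted over the list alone and 0 over all genes. Folr1, a folate transporter, stood at -3.73 ± 1.48 and Otx2, a transcription factor, at -3.22 ± 1.28. For choroid plexus the call was kept but with a mean of -5.06 without mutant male 1, and it was lost without the 3 lowest libraries (0.05, adjusted p = 0.801). Ependymal genes were lower in all 11 (mean log2 -0.73, camera adjusted p = 6.93e-06, adjusted p = 0.465 with an estimated correlation), with Foxj1, the regulator of motile cilia, at -0.67 ± 0.24. For ependyma the call was kept but with a mean of -0.43 without mutant male 2. It too was lost with the choroid plexus score as a covariate (-0.12, adjusted p = 0.509). Pericyte and smooth muscle markers were higher in 9 of 12 (mean log2 0.41, median 0.21, camera adjusted p = 0.0152, adjusted p = 0.634 with an estimated correlation). The contractile gene Cnn1 stood at 1.91 ± 0.74, from 5.93 to 7.59 normalized counts in wild-type males. For pericytes the call was lost without mutant male 2 (0.25, adjusted p = 0.0875) and mutant male 3 (0.33, adjusted p = 0.0728), and kept but with a mean of 0.65 without mutant male 1. A minimum mean of 50 also ended it (0.27, adjusted p = 0.0670). Without the 3 libraries lowest in choroid plexus markers, which left 1 mutant male, the mean was -0.06. Astrocyte markers had a mean log2 fold change of 0.06 (camera adjusted p = 0.0152, adjusted p = 0.634 with an estimated correlation), with the transporter Slc4a4 at 0.11 ± 0.05. For astrocytes the call was lost without wild-type male 1 (0.04, adjusted p = 0.122) and mutant male 3 (0.03, adjusted p = 0.279), and kept but with a mean of 0.10 without mutant male 1. Heat shock and folding genes were lower in 15 of 22 (mean log2 -0.07, camera adjusted p = 0.0218, adjusted p = 0.512 with an estimated correlation), with the endoplasmic reticulum chaperones Pdia4 at -0.29 ± 0.07 and Hspa5 at -0.23 ± 0.07. In this list 1 passed when adjusted over the list alone and 0 over all genes. For heat shock genes the call was lost without wild-type male 2 (-0.05, adjusted p = 0.146), wild-type male 3 (-0.07, adjusted p = 0.0516) and mutant male 1 (-0.07, adjusted p = 0.110).

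Single genes with the smallest p in males, none past the threshold of limma, were, on the higher side, Sema4f (0.21 ± 0.04, 15.7% higher), Ptpro (0.26 ± 0.05, 19.6% higher), Scg2 (0.22 ± 0.04, 16.1% higher), Pde1b (0.17 ± 0.04, 12.8% higher) and Tagln3 (0.15 ± 0.03, 11.3% higher). On the lower side, after Chd8, they were Dnah9 (-0.32 ± 0.05, 19.6% lower), Stxbp2 (-0.33 ± 0.06, 20.6% lower), Gpnmb (-0.59 ± 0.10, 33.5% lower) and Erbin (-0.25 ± 0.04, 15.9% lower). Of these DESeq2 called Erbin (0.00191), Scg2 (0.00403), Ptpro (0.00573), Pde1b (0.0148) and Tagln3 (0.0148). Sema4f encodes a semaphorin, Scg2 a secretory granule protein, and Dnah9 a motor protein of cilia. Gpnmb had 127 ± 2.18 normalized counts in wild-type and 84.5 ± 5.47 in mutant males.

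In females, mutants had higher levels of genes of fibroblasts, extracellular matrix and blood, and lower levels of myelin genes. No gene passed limma's threshold (smallest adjusted p = 0.584), and 1207 had an unadjusted p under 0.05 against 875 expected. Past 0.05 were 0 genes with edgeR, 0 with limma-voom and 11 (5 higher, 6 lower) with DESeq2, and 1 without the 3 libraries lowest in choroid plexus markers. Without mutant female 2 there was 1, Hjurp (0.45, adjusted p = 0.00445), and without mutant male 2, which only changes the shared variance, 1, Wdfy1 (-0.58, adjusted p = 0.00200). Of 38 lists, 14 were called (9 higher, 5 lower), with 0 called by an estimated correlation and 0 by fry (smallest adjusted p = 0.334).

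Of the 20 myelin genes 19 were lower in mutant females (mean log2 -0.22, camera adjusted p = 6.55e-13, adjusted p = 0.567 with an estimated correlation), all but Trf. None passed when adjusted over the list alone or over all genes. Mobp stood at -0.31 ± 0.09 (19.6% lower), Mbp, a core myelin protein, at -0.25 ± 0.09 (15.8% lower), Mog at -0.28 ± 0.09 and Hapln2 at -0.33 ± 0.11. All 3 mutant females scored below all 3 wild-type females, and a full separation in either direction has an exact permutation p of 0.1, the floor for 3 against 3.

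Fibroblast genes were higher in all 15 (mean log2 1.13, camera adjusted p = 1.36e-13, adjusted p = 0.407 with an estimated correlation; median 1.26), 12 of them past 0.05 when adjusted over the list alone and 0 over all genes. Col1a2 and Col1a1, fibrillar collagens, went from 649 to 1870 and from 385 to 1006 normalized counts (1.38 ± 0.38 and 1.26 ± 0.36), with the growth factor Igf2 at 1.32 ± 0.40 and Lum at 0.98 ± 0.29. Extracellular matrix genes were higher in 42 of 48 (mean log2 0.48, camera adjusted p = 4.25e-15, adjusted p = 0.407 with an estimated correlation), 16 past 0.05 when adjusted over the list alone and 0 over all genes, with Nid1, a basement membrane protein called by DESeq2 (0.0223), at 0.77 ± 0.20 and Thbs2 at 0.85 ± 0.22. The lists share 7 of the 15 fibroblast genes, and the matrix mean was 0.39 without these. With all 48 it was 0.30, adjusted p = 5.89e-08 without mutant female 2. All 5 red blood cell genes were higher (mean log2 0.70, camera adjusted p = 5.49e-07, adjusted p = 0.407 with an estimated correlation), 4 past 0.05 when adjusted over the list alone and 0 over all genes. Hbb-bt stood at 0.85 ± 0.22 and Hba-a1 at 0.77 ± 0.20; each has a near-identical copy, so reads are uncertain between copies. Endothelial markers were higher in all 14 (mean log2 0.17, camera adjusted p = 1.35e-05, adjusted p = 0.538 with an estimated correlation), with Kdr, a receptor for vascular growth factor, at 0.20 ± 0.06 and Tek at 0.22 ± 0.08. Their mean was 0.09, adjusted p = 0.0114 without mutant female 2. Choroid plexus genes had a mean of 1.69 in the same comparison. Pericyte and smooth muscle genes were higher in 11 of 12 (mean log2 0.42, camera adjusted p = 7.18e-04, adjusted p = 0.622 with an estimated correlation), with Pdgfrb, a pericyte receptor, at 0.34 ± 0.09, 2 past 0.05 when adjusted over the list alone and 0 over all genes. For pericytes the call was lost without mutant female 2 (0.13, adjusted p = 0.166).

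The remaining female lists depended on single libraries. Choroid plexus genes were higher in all 20 (mean log2 1.69, camera adjusted p = 5.07e-05, adjusted p = 0.764 with an estimated correlation), with Slc13a4 at 1.39 ± 0.47. For choroid plexus the call was lost without wild-type female 1 (0.10, adjusted p = 0.805), and kept but with a mean of 2.89 without wild-type female 3. Interferon response genes were higher in 20 of 24 (mean log2 0.25, camera adjusted p = 3.48e-04, adjusted p = 0.622 with an estimated correlation), with H2-K1, which presents antigen, at 0.35 ± 0.12, B2m at 0.22 ± 0.08 and the RNA sensor Ifih1 at 0.38 ± 0.17. For interferon genes the call was lost without wild-type female 1 (0.13, adjusted p = 0.122), and kept but with a mean of 0.40 without wild-type female 3. Activity-regulated genes had a mean log2 fold change of 0.07 (camera adjusted p = 0.0311, adjusted p = 0.622 with an estimated correlation), with Jun at 0.17 ± 0.05. For activity-regulated genes the call was lost without wild-type female 3 (0.01, adjusted p = 0.683), mutant female 2 (0.05, adjusted p = 0.0637) and mutant female 3 (0.06, adjusted p = 0.149), and kept but with a mean of 0.10 without wild-type female 1. Targets of Wnt had a mean log2 fold change of 0.12 (camera adjusted p = 0.0371, adjusted p = 0.622 with an estimated correlation), with Axin2, a feedback inhibitor of the pathway, at 0.13 ± 0.05. For Wnt targets the call was lost without wild-type female 2 (0.07, adjusted p = 0.258), mutant female 1 (0.12, adjusted p = 0.0580) and mutant female 2 (0.06, adjusted p = 0.408), and kept but with a mean of 0.18 without mutant female 3. Synaptic vesicle genes had a mean log2 fold change of -0.05 (camera adjusted p = 0.0461, adjusted p = 0.879 with an estimated correlation), with Vamp1 at -0.13 ± 0.04. For vesicle genes the call was lost without wild-type female 1 (0.01, adjusted p = 0.805) and mutant female 2 (-0.04, adjusted p = 0.433), and kept but with a mean of -0.08 without wild-type female 3.

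Ribosomal protein genes had a mean log2 fold change of -0.02 (camera adjusted p = 0.00634, adjusted p = 0.965 with an estimated correlation), with Rpsa at -0.12 ± 0.04. For ribosomal proteins the call was lost without wild-type female 2 (-0.00045, adjusted p = 0.783) and mutant female 2 (-0.02, adjusted p = 0.128), and kept but with a mean of -0.05 without wild-type female 1. Splicing genes had a mean log2 fold change of -0.02 (camera adjusted p = 0.0263, adjusted p = 0.705 with an estimated correlation), with the neuronal splicing factor Nova1 at -0.22 ± 0.07. For splicing genes the call was lost without wild-type female 1 (-0.02, adjusted p = 0.0660), wild-type female 3 (-0.02, adjusted p = 0.125), mutant female 1 (-0.02, adjusted p = 0.118) and mutant female 3 (-0.02, adjusted p = 0.149). Genes of cholesterol synthesis had a mean log2 fold change of -0.05 (camera adjusted p = 0.00308, adjusted p = 0.622 with an estimated correlation), with Cyp51, an enzyme of the pathway, at -0.15 ± 0.05. For cholesterol synthesis the call was lost without wild-type female 2 (-0.03, adjusted p = 0.0961) and mutant female 1 (-0.03, adjusted p = 0.0850), and kept but with a mean of -0.08 without wild-type female 1. Single genes with the smallest p in females, all with an adjusted p of 0.584 and none past the threshold of limma, were Pygm (0.33 ± 0.06, 25.7% higher), Kif7 (0.58 ± 0.12, 49.4% higher), Hjurp (0.34 ± 0.07, 26.5% higher), Bag3 (0.49 ± 0.10, 40.8% higher) and Serpinh1 (0.48 ± 0.10, 39.6% higher). On the lower side, after Chd8, they were Slc6a8 (-0.15 ± 0.03, 9.97% lower), 2610008E11Rik (-0.21 ± 0.04, 13.8% lower), Gm12940 (-0.27 ± 0.05, 16.9% lower) and Gprc5b (-0.16 ± 0.03, 10.5% lower). Of these DESeq2 called Hjurp (0.0149), Pygm (0.0185), Slc6a8 (0.0185), Serpinh1 (0.0188) and Gprc5b (0.0256). Pygm encodes muscle glycogen phosphorylase, Bag3 a co-chaperone and Serpinh1 a collagen chaperone. Gm12940 overlaps Sfpq on the same strand, and Kif7 and Gprc5b overlap genes on the other strand that these libraries could not separate.

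Whether the genotype difference was unlike in the sexes was tested as the male minus the female genotype effect. Fibroblast, extracellular matrix and red blood cell genes had lower values in that difference, and markers of pyramidal neurons and synaptic vesicles had higher ones. No gene passed limma's threshold (smallest adjusted p = 0.619), and 1373 had an unadjusted p under 0.05 against 875 expected. Past 0.05 were 0 genes with edgeR, 0 with limma-voom, 3 (1 higher, 2 lower) with DESeq2 and, with 1 mutant male library left, 2 without the 3 libraries lowest in choroid plexus markers. Without mutant male 2 there was 1, Wdfy1 (1.08, adjusted p = 2.01e-04). Of 38 lists, 16 were called (7 higher, 9 lower), with 0 called by an estimated correlation and 0 by fry (smallest adjusted p = 0.300). The myelin list was not called (-0.03, camera adjusted p = 0.757).

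Fibroblast genes had negative values in all 15 (mean log2 -1.27, camera adjusted p = 7.32e-09, adjusted p = 0.376 with an estimated correlation), with Igf2 at -1.97 ± 0.57 and Ogn at -2.10 ± 0.68. Extracellular matrix genes were negative in 40 of 48 (mean log2 -0.53, camera adjusted p = 6.81e-09, adjusted p = 0.394 with an estimated correlation), with Thbs1 at -1.68 ± 0.40, and a mean of -0.35, adjusted p = 3.37e-05 without mutant female 2. All 5 red blood cell genes were negative (mean log2 -0.88, camera adjusted p = 1.05e-05, adjusted p = 0.376 with an estimated correlation; exact permutation p = 0.0400, adjusted over 38 lists 0.412), 4 past 0.05 when adjusted over the list alone and 0 over all genes. Their scores were 8.24 ± 0.41 and 8.06 ± 0.08 in wild-type and mutant males, and 7.09 ± 0.31 and 7.79 ± 0.27 in wild-type and mutant females. Interferon genes were negative in 21 of 24 (mean log2 -0.41, camera adjusted p = 1.50e-04, adjusted p = 0.525 with an estimated correlation), with Bst2 at -1.65 ± 0.70 and Ifi27 at -1.15 ± 0.42, and a mean of -0.26, adjusted p = 0.0133 without wild-type male 1. Heat shock and folding genes were negative in 17 of 22 (mean log2 -0.15, camera adjusted p = 0.00125, adjusted p = 0.376 with an estimated correlation; exact permutation p = 0.005, adjusted over 38 lists 0.190), 2 past 0.05 when adjusted over the list alone and 0 over all genes, with Bag3 at -0.62 ± 0.14 and Pdia4 at -0.41 ± 0.11. Endothelial markers had a mean log2 fold change of -0.15 (camera adjusted p = 0.0163, adjusted p = 0.549 with an estimated correlation), with Kdr at -0.37 ± 0.09. For endothelial cells the call was lost without wild-type male 2 (-0.14, adjusted p = 0.0557), wild-type female 3 (-0.13, adjusted p = 0.136), mutant male 1 (-0.12, adjusted p = 0.112), mutant male 3 (-0.12, adjusted p = 0.0667) and mutant female 2 (-0.07, adjusted p = 0.242). Glucocorticoid response genes had a mean log2 fold change of -0.20 (camera adjusted p = 0.0315, adjusted p = 0.527 with an estimated correlation), with Sult1a1 at -0.98 ± 0.24. For glucocorticoid targets the call was lost without wild-type male 2 (-0.18, adjusted p = 0.126), wild-type male 3 (-0.17, adjusted p = 0.154), wild-type female 1 (-0.15, adjusted p = 0.170), wild-type female 3 (-0.23, adjusted p = 0.0600) and mutant male 1 (-0.17, adjusted p = 0.244).

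Pyramidal neuron markers were positive in all 10 (mean log2 0.15, camera adjusted p = 4.42e-04, adjusted p = 0.376 with an estimated correlation), with Slc17a7 at 0.16 ± 0.05. For pyramidal neurons the call was kept but with a mean of 0.09 without wild-type female 2 and 0.24 without wild-type female 3. Vesicle genes were positive in 29 of 32 (mean log2 0.13, camera adjusted p = 1.58e-08, adjusted p = 0.376 with an estimated correlation), with Syn1 at 0.16 ± 0.06. For vesicle genes the call was kept but with a mean of 0.07 without wild-type female 1. For the postsynaptic scaffold a mean log2 fold change of 0.07 (camera adjusted p = 4.88e-04, adjusted p = 0.527 with an estimated correlation) was found, with Nlgn3 at 0.23 ± 0.06. For scaffold genes the call was kept but with a mean of 0.11 without wild-type female 3 and 0.05 without mutant male 2. GABA receptor genes had a mean log2 fold change of 0.05 (camera adjusted p = 0.00168, adjusted p = 0.376 with an estimated correlation), with a median of 0.13, a lowest value of -1.02 and Gabra4 at 0.16 ± 0.06. With a minimum mean of 50 their mean was 0.12, adjusted p = 8.30e-04. For GABA receptors the call was kept but with a mean of 0.01 without mutant male 1. Glutamate receptor genes had a mean log2 fold change of 0.06 (camera adjusted p = 0.0187, adjusted p = 0.549 with an estimated correlation), with Grm2 at 0.30 ± 0.11. For glutamate receptors the call was lost without wild-type male 1 (0.05, adjusted p = 0.0603), wild-type female 1 (-0.01, adjusted p = 0.479), mutant male 2 (0.05, adjusted p = 0.0837), mutant male 3 (0.03, adjusted p = 0.0847) and mutant female 2 (0.04, adjusted p = 0.0663), and kept but with a mean of 0.11 without wild-type female 3 and 0.10 without mutant male 1. Immature neuron genes had a mean log2 fold change of 0.06 (camera adjusted p = 0.0435, adjusted p = 0.468 with an estimated correlation), with Elavl2 at 0.22 ± 0.10. For immature neurons the call was lost without wild-type male 2 (0.01, adjusted p = 0.0769), wild-type male 3 (0.04, adjusted p = 0.154), wild-type female 3 (0.05, adjusted p = 0.214), mutant male 1 (0.06, adjusted p = 0.195), mutant male 3 (0.05, adjusted p = 0.0659) and mutant female 3 (-0.02, adjusted p = 0.192), and kept but with a mean of 0.12 without wild-type male 1, 0.09 without wild-type female 1, 0.03 without wild-type female 2 and 0.13 without mutant female 2. Ribosomal protein genes had a mean log2 fold change of 0.04 (camera adjusted p = 0.00173, adjusted p = 0.803 with an estimated correlation), with Rpsa at 0.12 ± 0.06. For ribosomal proteins the call was lost without wild-type male 2 (0.02, adjusted p = 0.0894), wild-type female 2 (0.01, adjusted p = 0.231) and mutant male 1 (0.01, adjusted p = 0.244), and kept but with a mean of 0.06 without wild-type female 1, 0.08 without mutant male 2 and 0.02 without mutant male 3. In the same difference choroid plexus genes were negative in all 20 (mean log2 -5.05, camera adjusted p = 3.66e-15, adjusted p = 0.394 with an estimated correlation), 20 past 0.05 when adjusted over the list alone and 0 over all genes. Ependymal genes had a mean log2 fold change of -0.79 (camera adjusted p = 3.18e-04, adjusted p = 0.527 with an estimated correlation), with Foxj1 at -0.80 ± 0.34. For ependyma the call was kept but with a mean of -0.44 without wild-type female 1 and -0.50 without mutant male 2. With the choroid plexus score as a covariate the pyramidal list was still called with a mean of 0.02, adjusted p = 0.0148. Lost were the calls of vesicle genes (0.03, adjusted p = 0.0745), scaffold genes (-0.00048, adjusted p = 0.943), and GABA receptors (0.08, adjusted p = 0.1005). Glutamate receptors (-0.09, adjusted p = 0.1005) and ependyma (0.13, adjusted p = 0.120) lost theirs too.

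Across 17496 genes the male and female genotype effects had a Pearson correlation of -0.27 and a Spearman correlation of 0.01. Swapping genotype labels within each sex gave Pearson values from -0.60 to 0.57, 27 of 100 as far from 0, and 94 of 100 for Spearman. The Pearson value was -0.44 without wild-type female 3 and 0.09 without wild-type female 1, -0.05 without the 3 libraries lowest in choroid plexus markers, and -0.01 with fold changes from DESeq2. Single genes with the smallest p for the difference, all with an adjusted p of 0.619 and none past the threshold of limma, were Sema4f (0.28 ± 0.06), Tagln3 (0.22 ± 0.05), Taok1 (0.17 ± 0.04), Wdfy1 (0.85 ± 0.19) and A330008L17Rik (0.57 ± 0.13) on the higher side. On the lower side they were Pygm (-0.49 ± 0.08), Tmem176a (-0.63 ± 0.12), Serpinh1 (-0.77 ± 0.15), Trim56 (-0.63 ± 0.13) and Rbms1 (-0.63 ± 0.14). The 3 genes called by DESeq2 were Serpinh1 (0.0153), Wdfy1 (0.0161) and Pygm (0.0215). Taok1, Wdfy1 and Tmem176a overlap genes on the other strand.

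Sex differences were tested within each genotype, as a check of the labels and as an effect whose direction is known. Y-linked genes were high in all 6 males and low in all 6 females. Eif2s3y, a translation factor gene, had 1710 ± 223 normalized counts in wild-type and 1849 ± 150 in mutant males and 0 in every female, at least 649-fold and at least 553-fold higher. Gm29650 was at least 45.0-fold and at least 32.6-fold higher. Each floor allows 3 reads per library and covers counting error only. Ddx3y had 2196 ± 85.4 and 2202 ± 231 in males, Kdm5d 1219 ± 115 and 1164 ± 75.4, and Uty 743 ± 39.5 and 665 ± 31.5. In females Ddx3y stood at 0.579 and 0.376, Kdm5d at 7.52 and 7.08, and Uty at 16.7 and 18.6. Xist, the RNA that silences an X chromosome, had 33030 ± 1916 and 31179 ± 1238 in wild-type and mutant females against 24.7 and 28.1 in males. In wild type 8 genes passed limma's threshold (5 higher in males, 3 lower), 0 of them autosomal, and in mutants 11 did (5 higher, 6 lower), 1 of them autosomal, Pygm. DESeq2 counted 23 and 26, and without a filter on low genes 13 passed in each genotype. Leaving out wild-type male 2 gave 13 in wild type, and leaving out the 3 libraries lowest in choroid plexus markers gave 19 in mutants, with 1 mutant male library.

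Among genes that escape X inactivation, Eif2s3x and Kdm6a were lower in males of both genotypes, and Kdm5c and Ddx3x passed in mutants. In wild type and mutants the log2 values, male minus female, were Eif2s3x (-0.57 and -0.55, adjusted p = 7.06e-06 and 1.09e-05), Kdm6a (-0.55 and -0.51, adjusted p = 1.05e-04 and 2.40e-04), Kdm5c (-0.24 and -0.34, adjusted p = 0.0941 and 0.00431) and Ddx3x (-0.27 and -0.35, adjusted p = 0.1002 and 0.00952). The others of the list were 5530601H04Rik (-0.27 and -0.25), Pbdc1 (-0.14 and -0.07) and Utp14a (-0.10 and -0.12). Tsix, which lies opposite Xist, stood at -0.05 and -0.44, in libraries that keep no strand.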

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

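Chosen only after the result was seen were the tests of genotype as the whole cause of the choroid plexus differences, of choroid plexus amount behind the myelin and fibroblast results, of white matter amount, of 1 mutant female library alone, the splits for the correlation of male and female effects, and the alternatives with a choroid plexus covariate, without 3 libraries and with thinned reads.

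The results given here are the 16 gene lists whose male minus female genotype effect was called, picked by that test of the difference between the sexes. With an estimated correlation 0 of them were called, with 0.376 the smallest adjusted p. They were pyramidal neurons (0.15), immature neurons (0.058), endothelial cells (-0.15), choroid plexus (-5.05), ependyma (-0.79), fibroblasts (-1.27), red blood cells (-0.88), synaptic vesicles (0.13), postsynaptic scaffold (0.074), glutamate receptors (0.061), GABA receptors (0.048), extracellular matrix (-0.53), ribosomal proteins (0.036), interferon response (-0.41), glucocorticoid response (-0.20) and heat shock genes (-0.15), as mean log2 values. Of 100 splits of the same libraries, 23 called at least as many lists as the real 16, with 21 the highest of the others, so a number this large could arise from grouping alone.

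Choroid plexus markers differed between the libraries of mutant males and of wild-type females. Different amounts of choroid plexus tissue fit: 11 of 12 further choroid plexus genes outside the list had their 3 lowest libraries in wild-type female 1, mutant male 2 and mutant male 3. Genotype cannot be the whole cause of differences within a group, whose libraries share it. Wild-type females alone ranged over 5.60 log2 units. The genotype differences of group means were -3.36 in males and 1.69 in females. How the tissue was taken is not in the labels, so dissection could not be examined directly.

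Fibroblast genes were higher in mutant females by 1.13 in the mean. More meningeal or vascular tissue fits, since matrix genes made by neural cells had a median of -0.046 in the same comparison, although a genotype effect limited to fibroblasts could give that too. Choroid plexus amount was excluded, as the value was 1.14 with its score as a covariate. The share of a single library is still open: without mutant female 2 the value was 0.81, still called. All 3 mutant females (mean score 9.61) lay above all wild-type females (8.48). Wild-type and mutant males had mean scores of 9.11 and 8.98.

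Myelin genes were lower in mutants of both sexes by a mean of -0.23. With reads thinned to the smallest library the value was -0.23. Thinning leaves the ratio of well-counted genes almost unchanged, so it could not decide on depth. With the choroid plexus score as a covariate, with 1 slope for all groups, the value was -0.24. That score was lower in mutant males (7.20 against 10.55) and higher in mutant females (9.92 against 8.24). A single slope could therefore not lower myelin genes in both sexes. Slopes that differ between groups were not tested. Less white matter in the mutant samples is still open: precursor genes moved by -0.069, a smaller amount, but an effect on myelination could give the same outcome. Since all 6 mutant libraries were sequenced less deeply, a batch shared with genotype may also have contributed, and thinning only equalizes read numbers.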

How the results depend on the processing

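Chosen only after the result was seen were the choroid plexus covariate, the set without 3 libraries and the thinned reads. Mutant libraries were less deeply sequenced, groups held 3 libraries, and the labels do not say that these came from separate animals. Calls of gene lists rest on the preset correlation: with an estimated correlation 0 lists were called in males, 0 in females, 0 for the interaction and 0 averaged, and with fry 0, 0, 0 and 0, with the cause not tested.

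Values that differ from the text include the following, by setting. Upper-quartile factors: 0 genes averaged, Chd8 -0.23 averaged (adjusted p = 0.0672), 0.026 for its interaction and 0.0023 between mutant sexes. Library totals: Chd8 0.015 between wild-type sexes. No filter: 0 genes averaged, 13 between wild-type sexes, Chd8 -0.22 (adjusted p = 0.0538). DESeq2: 35 genes in males, 11 in females, 3 for the interaction, 75 averaged, 23 and 26 between the sexes in wild type and mutants, Chd8 -0.23 in males (adjusted p = 6.47e-04) and -0.22 in females (adjusted p = 0.0129), and a correlation of -0.0083 from its fold changes. Mean of at least 50: neuropeptides 0.077 and pericytes 0.27 in males, synaptic vesicles -0.048 in females, GABA receptors 0.040 and postsynaptic scaffold 0.021 averaged were not called, and GABA receptors were 0.12 for the interaction and neuropeptides 0.062 averaged. Thinned reads: Wnt targets 0.11, synaptic vesicles -0.046 and splicing genes -0.018 in females, immature neurons 0.062 for the interaction and postsynaptic scaffold 0.020 averaged were not called. Chd8 between wild-type sexes was 6.2e-04 with limma-voom and 0.0014 with edgeR. With 1 surrogate variable: Spag16 0.41, Hydin 0.010 and Sgk1 0.035 for the interaction, Tsix 0.27 between mutant sexes and Chd8 0.0017 between wild-type sexes.

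Replicate numbers are shared across groups. As a block they gave 0 genes averaged, 9 and 11 between the sexes in wild type and mutants, 15, 14, 16 and 21 lists in males, females, interaction and averaged, and Chd8 -0.22 (adjusted p = 0.131). Of 12 libraries 3 correlated best with their own number, and 4 of 18 same-number pairs had a correlation above 0.1, so the numbers were not used as pairs.

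With the choroid plexus covariate: Foxj1 0.014, Spag16 0.50, Hydin 0.037, Sgk1 0.046, ependyma 0.13, postsynaptic scaffold -4.8e-04 and glutamate receptors -0.094 for the interaction; Tsix 0.37 between mutant sexes, Chd8 0.0017 between wild-type sexes; astrocytes -0.033, activity-regulated genes -0.0036 and glutamate receptors -0.055 in males; synaptic vesicles -0.0013 averaged. With it synaptic vesicles -0.015 and splicing genes -0.018 in females were not called, and activity-regulated genes 0.10 and ribosomal proteins -0.045 in females, immature neurons 0.089 and ribosomal proteins 0.099 for the interaction, and ependyma -0.18 averaged still were.

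Without the 3 libraries, where mutant males had 1: 12 genes in males, 1 in females, 2 for the interaction, 82 averaged, 19 between mutant sexes, correlation -0.050; Myh11 -0.39, Enpp2 0.027, Folr1 0.034, Trpv4 0.011, astrocytes -0.019, pericytes -0.063, choroid plexus 0.049 and glutamate receptors -0.025 in males; synaptic vesicles 0.0073 in females; Spag16 0.51, Hydin 0.016, ependyma 0.091 and glutamate receptors -0.085 for the interaction; Enpp2 0.0011, Sostdc1 0.080 and choroid plexus 0.072 averaged; Tsix 0.99 between mutant sexes and Chd8 0.0031 between wild-type sexes. Also not called then were activity-regulated genes 0.021, postsynaptic scaffold 0.0084 and ependyma -0.20 in males; choroid plexus 0.095, splicing genes -0.018 and interferon genes 0.13 in females; choroid plexus -0.047 and postsynaptic scaffold 0.0066 for the interaction; and inhibitory neurons 0.028, astrocytes 0.035 and postsynaptic scaffold 0.0051 averaged. Still called but moved were myelin -0.43, pyramidal neurons 0.091, GABA receptors 0.16 and neuropeptides 0.40 in males. In females these were activity-regulated genes 0.10, ribosomal proteins -0.046 and cholesterol synthesis -0.076. For the interaction they were pyramidal neurons 0.052, immature neurons 0.098, synaptic vesicles 0.046, GABA receptors 0.11 and ribosomal proteins 0.10. Averaged, they were myelin -0.35, precursors -0.12, pericytes 0.19, fibroblasts 0.30, synaptic vesicles 0.030, GABA receptors 0.11, neuropeptides 0.28, matrix 0.12 and cholesterol synthesis -0.055.

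Leaving out 1 library at a time gave 0 to 1 genes in males, females and the interaction, 0 to 8 averaged, 8 to 13 and 9 to 14 between the sexes in wild type and mutants, and 12 to 19, 11 to 15, 12 to 18 and 14 to 22 lists in males, females, interaction and averaged. Chd8 was -0.26 to -0.20 in males, -0.23 to -0.20 in females, -0.24 to -0.21 averaged, -0.047 to 0.014 for the interaction and -0.034 to 0.027 between wild-type sexes. Tsix was -0.37 to 0.25 and -1.16 to 0.24 between the sexes in wild type and mutants. Synaptic vesicles were -0.085 to 0.0073 in females and -0.0031 to 0.043 averaged, glutamate receptors -0.011 to 0.11 and immature neurons -0.025 to 0.13 for the interaction, and the correlation was -0.44 to 0.094. Other settings changed no call of a gene in the genotype comparisons.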

Other observations

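Chosen only after the values were seen were the comparison of 2-level genes and of DESeq2 calls below.

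Some genes stood at 2 separate levels across the 12 libraries. Ide, which encodes a protease that degrades insulin, had 1469 to 1584 normalized counts in 6 libraries and 2177 to 2244 in the other 6, and Morc2a had 1573 to 1754 or 2288 to 2379, with both levels present in every group. Wdfy1 had 985 to 1159 or 1531 to 1657. It was low in all wild-type males, high in all wild-type females, low in all mutant females and high in mutant males 1 and 3 but not 2. Without mutant male 2 it passed in males, females and the interaction. These 3 genes were chosen after their values were seen.

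For 4 genes in no fixed list, picked from the averaged calls of DESeq2 and of the set without 3 libraries, where mutant males had 1, values are given without a test of them as a group. Sox10, a transcription factor, stood at -0.22 and -0.33 in these, Gjc3, a gap junction protein, at -0.26 and -0.34, Anln at -0.31 and -0.42, and Nfasc, which anchors the paranode, at -0.21 and -0.30. They were picked after their values were seen. DESeq2 called 75 genes, 8 of them in the myelin list, the set without 3 libraries called 82, 15 of them in the list, and 34 were called by both.

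Splits of the same libraries into groups of the same sizes gave the share of arrangements with a result as large as the real one. For the genotype effect averaged over the sexes 3 of 100 gave at least the 1 gene found, with 6 the highest of the others, and 3 of 100 gave at least the 20 lists called, with 21 the highest. For the difference between the sexes all 100 gave at least 0 genes, with 2 the highest. For the correlation of male and female effects 27 of 100 lay as far from 0 as -0.27, with -0.60 the farthest. With only 10 splits, too few for a share under 0.05, males had 10 of 10 for 0 genes (highest other 0) and 3 of 10 for 14 lists (18), females 10 of 10 for 0 genes (0) and 6 of 10 for 14 lists (19). In the comparison of sexes 1 of 10 reached 8 genes in wild type (0) and 1 of 10 reached 11 in mutants (0).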
